A study of Arabidopsis thaliana with 6 samples.

How the data were processed

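The series holds RNA-seq of fresh Arabidopsis thaliana seeds from the wild type Columbia-0 (Col-0, 3 libraries) and from the asf1a1b double mutant (3 libraries), which carries mutations in both genes for the histone chaperone ASF1. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, fresh seeds were harvested within a day, total RNA was extracted with a plant RNA kit, and libraries were built by a sequencing company. The same labels also mention cold stratification under growth conditions, so whether the sequenced seeds had been stratified is not settled by them. Nothing in the labels says whether the 3 libraries of a genotype came from separate plants or harvests, so the p-values measure only the spread between these samples, which may be technical.

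Per the submitters' processing notes, fastp 0.23.4, HISAT2 2.2.1 and the TAIR10 build were used. The read counter, the gene annotation, the strand setting and the test behind the authors' comparison table are not given in the sources used here. The authors deposited a table of 32833 genes that its name calls TPM. Its library totals run from 915126 to 1049698, where plain TPM would give 1 total for all, so the deposited signal values are TPM rescaled between libraries, by a step that no source names. They are called rescaled TPM here. A second deposited table gives, for 15257 genes, the authors' log2 fold change, p-value and adjusted p-value, a direction call, and the same values per library (largest difference 0). Columns of other samples were not present (0 columns unused).

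Multiplying a deposited value by the gene's merged exon length, from the RefSeq annotation of TAIR10.1, gave whole multiples of 1 step per library. Of the values under 200 reads whose rounding allowed the check, 99.35% to 99.45% per library lay within 0.1 of a whole number. The steps were used to recover reads for 32548 genes. The other 285 are organelle loci without a matched length. The recovered totals were 47993501, 44306792 and 47369953 reads in Col-0 replicates 1, 2 and 3, and 42771256, 56017624 and 52690995 in asf1a1b replicates 1, 2 and 3. Whether the authors counted reads or read pairs is not known. On simulated whole reads, the same code recovered 100.0% of the read numbers from 1 to 199 exactly in each library, over 32548 genes. Floors based on these reads use 3 counts and cover counting error only.

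The design fixed before the data were examined foresaw raw counts or plain TPM. The values were neither, and the test foreseen for TPM was used. Genes with a mean of at least 1 over the 6 libraries (14663) were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), genotype as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change is on the log2(value + 1) scale, which understates the change of low genes. Fold differences given as "times" are ratios of group means of the deposited values. Gene lists (22 lists, 468 entries, all found in the files) were fixed before the data were examined. The 16 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

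The named genes follow a rule fixed beforehand. ASF1A, ASF1B and PRX69 are always named. The 10 largest log2 fold changes up and the 10 down are taken among genes with adjusted p under 0.05, a mean of at least 5 in the higher group and no overlap between the groups. From each list, up to 4 members past the threshold with the largest absolute change are taken. The rule took nuclear protein-coding genes only, 78 in all, of which 1 is not reported here. Their groups do not overlap, a property that chance gives to 10% of genes and that 47.5% of the tested genes had. Of the 78, 12 overlap another annotated gene, among them HTB9, FLC, HSFA9 and LHCB1.3, and without a known strand setting their reads cannot be told from those of the neighbour. Histone, 2S albumin and LHCB1 genes have near-identical copies between which reads can be split, so values of single copies are uncertain. Symbols come from the RefSeq table of TAIR10.1, where 32548 identifiers matched, or from the fixed lists. A symbol shared by several genes was given to the list gene only.

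The deviations of same-numbered libraries from their group means correlated across the 14663 genes at 0.427 for replicate 1, 0.144 for replicate 2 and 0.327 for replicate 3. All are above 0.1, so by the rule set beforehand the numbers pair the samples, although no label names a shared batch and asf1a1b replicate 2 correlated more with Col-0 replicate 3 (0.381). The replicate block was an alternative fit. Replicate libraries differed by far more than sampling noise (a median chi-square per gene of 2.54 or more for each pair of the same genotype, over 14517 genes), so none was treated as a repeat deposit.

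The alternatives were the replicate block, leaving out each library, a pseudocount of 0.1, no filter beyond a mean above 0, a mean of at least 5, median-of-ratios scaling, leaving out the 20 highest genes, limma without the trend, and for the lists an estimated correlation or fry. After seeing the data, limma-voom on the recovered reads was added, with library sizes set so that the scaling equals that of the deposited values. On simulated data for the 14663 genes of this comparison, limma recovered 68% of 100 genes changed by 1 on the log2 scale and 91% of 100 genes changed by 2, and 4.73% of its calls were false. The limma-voom step, on 14438 genes, recovered 98.9% of 92 genes changed by 1 and 100% of 98 changed by 2, and 8.25% of its calls were false. Its simulation gave every gene the same dispersion and changed only genes above a set read number. The limma simulation used the spread of each gene. The percentages of the limma and limma-voom simulations therefore cannot be compared.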

Results

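RNA-seq libraries from fresh seeds of wild-type Col-0 and of the asf1a1b double mutant were compared, with 3 libraries per genotype. ASF1 proteins are chaperones that carry histones H3 and H4 to chromatin. The series title names germination and the class III peroxidase gene PRX69 as the subject, and the comparison asks which transcripts differ between mutant and wild-type seeds. Values are rescaled TPM as deposited. The reads recovered from them numbered 44306792 to 47993501 per Col-0 library and 42771256 to 56017624 per asf1a1b library. A value of at least 1 was found for 13988 to 14213 genes in Col-0 and for 14622 to 14923 genes in asf1a1b.

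Both targeted genes were low in every mutant library. ASF1A (AT1G66740, chromosome 1, 24892340 to 24893876 on the plus strand of TAIR10.1, 3 exons) had 16.7 ± 1.23 rescaled TPM in Col-0 and 2.33 ± 0.237 in asf1a1b (SD, n = 3), a log2 fold change of -2.41 ± 0.12 (SE, limma adjusted p = 0.00022). ASF1B (AT5G38110, chromosome 5, 15208358 to 15210335 on the plus strand, 3 exons) had 2.97 ± 1.21 in Col-0 and 0.256 ± 0.0902 in asf1a1b (SD, n = 3; log2 fold change -1.62 ± 0.22, limma adjusted p = 0.00276). The remaining signal in the mutant came from 288 recovered reads for ASF1A and 32 for ASF1B over the 3 libraries, against 1985 and 367 in Col-0.

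PRX69 (AT5G64100, chromosome 5, 25650567 to 25652247 on the minus strand of TAIR10.1, 3 exons) went the other way. It was listed at 0 in all 3 Col-0 libraries and had 1.104, 4.153 and 6.011 rescaled TPM in asf1a1b replicates 1, 2 and 3, from 47, 251 and 310 recovered reads. The 0 reads over the Col-0 group allow up to 0.0204 rescaled TPM at a floor of 3 counts over the group. The asf1a1b mean of 3.76 ± 2.48 (SD, n = 3) was 184 times that floor. The floor covers counting error in Col-0 only, not the spread between the mutant libraries. On the log2(value + 1) scale the change was 2.08 ± 0.40 (SE, limma adjusted p = 0.00887). The authors' deposited table gives PRX69 a log2 fold change of 9.95 and an adjusted p of 3.64e-12. The adjacent peroxidase genes on the same strand were low. PRX70 (AT5G64110) had 0 recovered reads in Col-0 and 0, 2 and 2 in the mutant libraries, and PRX71 (AT5G64120) had 1, 0 and 0 reads in Col-0 and 18, 35 and 28 in the mutant. Both were below the level tested. The neighbour on the other side, AT5G64090, had a mean of 16.1 in Col-0 and 12.6 in asf1a1b and did not pass the threshold (limma adjusted p = 0.0813). Beyond PRX71, AT5G64130, singled out after its values were seen, rose from a mean of 6.76 to 21.3 (limma adjusted p = 0.00147).

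**Figure D1:**
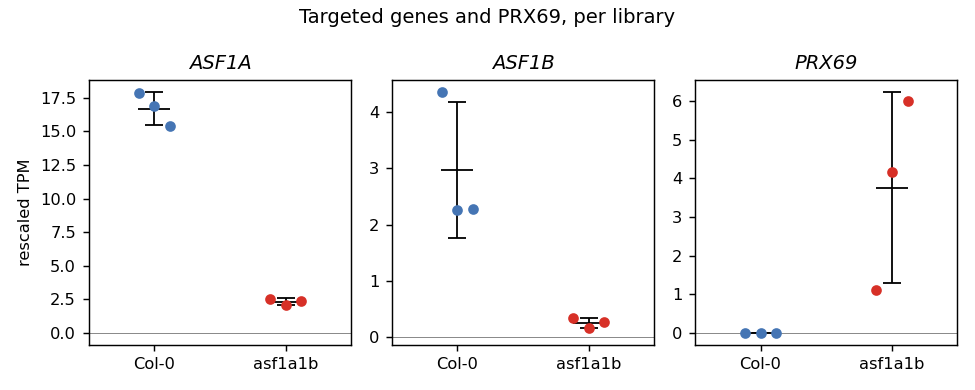
Rescaled TPM (vertical axis, linear, one scale per panel) of ASF1A, ASF1B and PRX69 in the 3 Col-0 (blue) and 3 asf1a1b (red) libraries; bars are mean and SD. ASF1A and ASF1B were lower in every mutant library, and PRX69 was at 0 in every Col-0 library and between 1.104 and 6.011 in the mutant.

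Class III peroxidases, a family of secreted enzymes that act on cell walls and hydrogen peroxide, were mostly low in these seeds, with 10 of 73 members at a mean of at least 1. Of the 73 members, 13 had no recovered read in any library, 18 had reads in asf1a1b alone, 0 in Col-0 alone and 42 in both. These are low counts, with under 20 reads over the 3 mutant libraries for 17 of the 18. With reads thinned to equal totals the numbers were 14, 19, 1 and 39, and without asf1a1b replicate 2, which had the most genes read in the mutant alone, they were 18, 15, 4 and 36. Some members read in both genotypes differed widely, among them PRX52 (13 reads over the Col-0 libraries and 245 over the asf1a1b libraries) and PRX55 (12 and 271). These were singled out after their values were seen. The authors' deposited table marks both as up, and also PRX62 and PRX66. PRX12, PRX31, PRX43 and PRX65 had fewer reads in asf1a1b. Of the 10 measured members, 5 rose, among them PRX69, 1 fell and 4 did not pass (5 rose and 2 fell when adjusted over the list alone). PRX42 (AT4G21960) rose from 10.7 ± 1.63 to 30.1 ± 2.71 and PRX36 (AT3G50990), a gene of seed coat mucilage cells, from 0.819 ± 0.653 to 5.35 ± 1.33 (SD, n = 3; limma adjusted p = 0.00127 and 0.00355). The ratio for PRX36 was 6.53, and 12.1 without Col-0 replicate 1. PRX34 (AT3G49120) had a mean of 14.9 with an SD of 16.0 in the mutant, and its call ended in all fits that left out 1 library but the one without asf1a1b replicate 1 (limma adjusted p up to 0.122, log2 fold change 2.70, without asf1a1b replicate 3) and with limma-voom on recovered reads (adjusted p = 0.0782). The ratio of means for PRX34 was 39.7, and 16.1 without asf1a1b replicate 2. The list itself did not pass (camera adjusted p = 0.161), though it did without Col-0 replicate 1, 2 or 3 or asf1a1b replicate 1 (camera adjusted p = 0.0186, 0.0147, 0.0259 and 0.0337). Over all libraries it had an adjusted p = 0.83 with an estimated correlation.

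Over all genes, 4494 of the 14663 tested differed between the genotypes, 2362 higher and 2132 lower in asf1a1b (limma, adjusted p under 0.05). The larger side depended on the setting, with 2044 higher and 2630 lower under median-of-ratios scaling and 1222 higher and 1322 lower among genes with a mean of at least 5. A change of at least 2-fold was seen for 1311 of them, 809 up and 502 down. The first principal component, with 69.5% of the variance, separated the genotypes, and the second, with 18.9%, separated replicate 1 from replicates 2 and 3 in both. The number of calls depended on single libraries. It was 2122 without Col-0 replicate 2, 2346 without asf1a1b replicate 2 and 1767 without asf1a1b replicate 3.

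**Figure D2:**
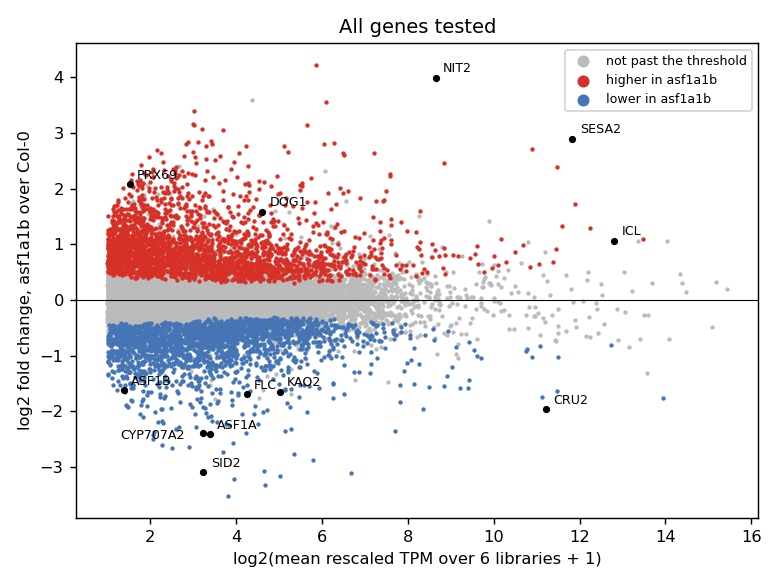
Log2 fold change of asf1a1b over Col-0 (vertical axis) against the log2 of the mean rescaled TPM plus 1 (horizontal axis) for the 14663 genes tested, with the 2362 genes higher in asf1a1b in red, the 2132 lower in blue and the rest in grey; black points mark named genes.

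NIT2 (AT3G44300), a nitrilase, led the 10 largest increases taken by the rule for named genes and rose 16.6 times, from 45.6 ± 22.3 to 757 ± 376 rescaled TPM (SD, n = 3; limma adjusted p = 0.00209). AGT3 (AT2G38400), an alanine:glyoxylate aminotransferase, rose 14.3 times, GLY3 (AT1G53580), named a glyoxalase in the annotation, 13.1 times, and AT2G25450, a 2-oxoglutarate-dependent dioxygenase, 49.0 times from a Col-0 mean of 0.283. PSK4 (AT3G49780), a precursor of the peptide hormone phytosulfokine, rose 28.7 times, the transcription factor gene WRKY75 (AT5G13080) 13.4 times, and XTH22 (AT5G57560), a cell wall xyloglucan enzyme, 25.5 times. The defensin-like gene PDF1.4 (AT1G19610), the 2S albumin gene SESA2 (AT4G27150) and the lipid transfer protein gene LTP3 (AT5G59320) complete the 10. LTP3 had a mean of 12.6 with an SD of 13.7 in the mutant and, of the fits that left out 1 library, kept its call only without asf1a1b replicate 1 (limma adjusted p up to 0.151 in the others, log2 fold change 2.61, without asf1a1b replicate 3). Its adjusted p was 0.0952 with limma-voom on recovered reads, 0.0559 with a mean of at least 5 and 0.089 with no filter. Single libraries weighed on some ratios of means. Without Col-0 replicate 1 the ratio was 49.9 for PSK4 and 21.8 in place of 5.92 for PDF1.4, and without asf1a1b replicate 2 it was 16.1 for XTH22 and 45.6 in place of 111 for LTP3. PDF1.4 lost its call in 3 of those fits, without Col-0 replicate 2, asf1a1b replicate 2 or asf1a1b replicate 3 (limma adjusted p up to 0.0782, log2 fold change 2.90).

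Among the 10 largest decreases, AT4G20820, a berberine-type FAD-binding protein gene, fell from 25.0 ± 7.83 to 1.26 ± 0.714 rescaled TPM (SD, n = 3; limma adjusted p = 0.000667). SID2 (AT1G74710), the isochorismate synthase of salicylic acid production, was 17 times lower, at 15.9 ± 5.12 in Col-0 and 0.940 ± 0.284 in asf1a1b. PYL12 (AT5G45870), of the abscisic acid receptor family, was 17.1 times lower. MSRB4 (AT4G04810), a methionine sulfoxide reductase, fell from 44.1 ± 2.04 to 4.34 ± 0.196, with an adjusted p of 3.18e-05 in limma, and GSTF9 (AT2G30860), a glutathione S-transferase, was 7.56 times lower. The others were AT4G35160 (an O-methyltransferase family gene, 12.2 times), AT1G68240 (a basic helix-loop-helix gene, 11.1 times), AT5G53260 (a seed maturation protein gene, 8.18 times), AT3G53960 (a transporter of the major facilitator type, 8.81 times) and AT4G29020 (a glycine-rich protein gene, 6.85 times). Without asf1a1b replicate 1, AT4G35160, AT5G53260 and AT4G29020 were 18.9, 16.2 and 10.6 times lower, and without Col-0 replicate 1 AT5G53260 was 5.405 times lower.

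Single regulators of dormancy and of abscisic acid and gibberellin, the hormones that hold back and promote germination, changed, and their lists did not pass. DOG1 (AT5G45830), a central dormancy gene, rose from 11.2 ± 1.31 to 35.6 ± 4.26 rescaled TPM (SD, n = 3; log2 fold change 1.58 ± 0.14, limma adjusted p = 0.000827). CYP707A2 (AT2G29090), an abscisic acid 8'-hydroxylase that degrades the hormone in seeds, fell from 14.8 ± 7.75 to 1.96 ± 1.32 (limma adjusted p = 0.005), 7.56 times lower and 12.3 times lower without asf1a1b replicate 1, while its homologue CYP707A1 (AT4G19230) rose from 2.52 to 4.81. KAO2 (AT2G32440), an ent-kaurenoic acid oxidase of gibberellin synthesis, fell from 48.0 ± 5.11 to 14.6 ± 1.55 (limma adjusted p = 0.000666). RGL2 (AT3G03450), a DELLA repressor of germination, rose from 8.24 ± 0.617 to 17.9 ± 1.44, and RGL3 (AT5G17490), another DELLA gene, fell from 32.7 to 17.5. ABI4 (AT2G40220), an abscisic acid response factor, fell from 4.79 ± 0.963 to 1.91 ± 0.140. Smaller calls were ABA3 (AT1G16540) up and NCED9 (AT1G78390) and ABI2 (AT5G57050) down, with log2 fold changes of 0.39, -0.49 and -0.40.

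Of 21 measured members of the dormancy and abscisic acid signalling list, 1 rose, 2 fell and 18 did not pass (1 and 1 when adjusted over the list alone; camera adjusted p = 0.722). Of 11 in abscisic acid synthesis and catabolism, 2 rose, 2 fell and 7 did not pass (2 and 2 when adjusted over the list alone; camera adjusted p = 0.534). Of 14 in gibberellin metabolism and signalling, 1 rose, 2 fell and 11 did not pass (1 and 2 when adjusted over the list alone; camera adjusted p = 0.534). When 1 library was left out, ABA3 kept its call only without asf1a1b replicate 1, CYP707A1 only without Col-0 replicate 1, NCED9 only without Col-0 replicate 1 or asf1a1b replicate 2, and ABI2 in no such fit, and RGL3 lost its call without Col-0 replicate 2, asf1a1b replicate 2 or asf1a1b replicate 3. The limma adjusted p of ABA3, CYP707A1, ABI2, NCED9 and RGL3 was then up to 0.158, 0.1, 0.118, 0.154 and 0.0781, with log2 fold changes of 0.34, 0.56, -0.41, -0.41 and -0.90, and ABA3 also lost its call under both other scalings (limma adjusted p = 0.077 and 0.0794). NCED9 and ABI2 lost theirs with the 20 highest genes left out (limma adjusted p = 0.0588 and 0.0509), NCED9 also with a mean of at least 5 (0.0591), ABI2 also without the trend (0.0517), and NCED9 and CYP707A1 with no filter (0.0705 and 0.0724).

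**Figure D3:**
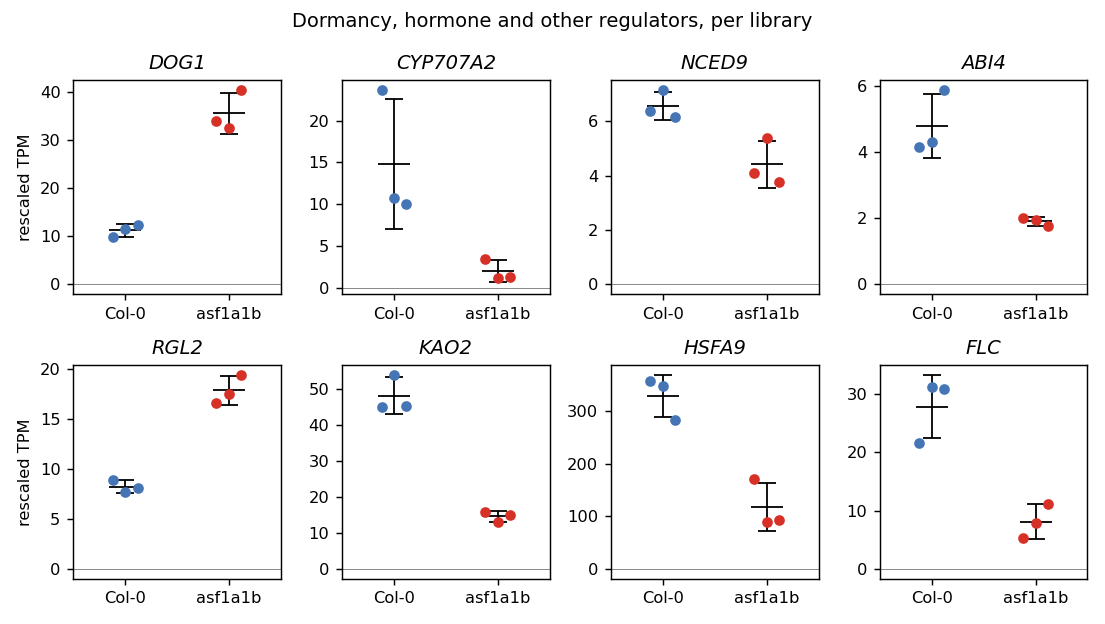
Rescaled TPM (vertical axes, linear, one scale per panel) of 8 regulators in the 3 Col-0 (blue) and 3 asf1a1b (red) libraries; bars are mean and SD. DOG1 and RGL2 were higher, and CYP707A2, NCED9, ABI4, KAO2, HSFA9 and FLC lower, in all 3 mutant libraries than in any Col-0 library.

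Among storage protein genes, the 2S albumin genes SESA1 (AT4G27140), SESA2 and SESA4 (AT4G27170) rose 4.89, 5.34 and 3.33 times, and the cruciferin gene CRU2 (AT1G03880) fell from 3784 ± 274 to 1012 ± 376 rescaled TPM (SD, n = 3; limma adjusted p = 0.00294). AT1G03890, a further cruciferin-type gene named after its values were seen, rose from 179.2 ± 77.9 to 403 ± 81.7 (limma adjusted p = 0.0187). The cruciferin genes CRA1 and CRU3 and the 2S albumin genes SESA3 and SESA5 did not pass (limma adjusted p = 0.606, 0.517, 0.346 and 0.555). SESA2 lost its call without asf1a1b replicate 3 (limma adjusted p = 0.0623, log2 fold change 2.78), and its ratio of means was 12.4 without Col-0 replicate 1. Of 18 genes of storage proteins and oil bodies, 4 rose, 1 fell and 13 did not pass (4 and 1 when adjusted over the list alone; camera adjusted p = 0.534). Of 23 LEA protein genes, which protect drying cells, 1 rose, 0 fell and 22 did not pass (1 and 0 when adjusted over the list alone; camera adjusted p = 0.392, and 0.0378 downwards without asf1a1b replicate 1; over all libraries, adjusted p = 0.83 with an estimated correlation). The riser was AT3G02480, from 487 ± 74.5 to 3286 ± 1050 (limma adjusted p = 0.0012). Among 21 heat shock genes, 3 rose and 4 fell (3 and 4 when adjusted over the list alone; camera adjusted p = 0.534). HSFA9 (AT5G54070), a seed-specific heat shock factor, fell from 330 ± 40.2 to 118 ± 45.3 (limma adjusted p = 0.00528), with HSP23.6-MITO (AT4G25200) at 404.5 and 154 and HSP21 (AT4G27670) at 32.1 and 11.9, and HSP18.2 (AT5G59720) rose from 2.24 to 5.27. The call of HSP23.6-MITO ended without Col-0 replicate 2 or asf1a1b replicate 2, and those of HSP21 and HSP18.2 without Col-0 replicate 2 or 3 or asf1a1b replicate 2 or 3 (limma adjusted p up to 0.0638, 0.1 and 0.106, log2 fold changes there -1.47, -1.19 and 0.88).

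Of 14 measured genes for mobilising oil, 6 rose, 0 fell and 8 did not pass (6 and 0 when adjusted over the list alone). ICL (AT3G21720) and MLS (AT5G03860), the enzymes of the glyoxylate cycle, had 4607 ± 555 and 1660 ± 236 rescaled TPM in Col-0 and 9693 ± 1900 and 2582 ± 320 in asf1a1b (SD, n = 3), and PCK1 (AT4G37870) and ACX2 (AT5G65110) rose 1.77 and 1.57 times. The list passed with camera (adjusted p = 0.0295) but not with an estimated correlation (adjusted p = 0.644). Its camera adjusted p was 0.074 without Col-0 replicate 1 and 0.0585 with no filter beyond a mean above 0. The call of MLS ended whichever library was left out, that of ICL without Col-0 replicate 2 or 3 or asf1a1b replicate 2 or 3, that of PCK1 without Col-0 replicate 1 or 2 or asf1a1b replicate 2 or 3, and that of ACX2 without asf1a1b replicate 3 (limma adjusted p for MLS, ICL, PCK1 and ACX2 up to 0.156, 0.11, 0.151 and 0.0512, log2 fold changes there 0.57, 0.96, 0.68 and 0.63), and the calls of MLS and PCK1 also ended under both other scalings. Of 7 measured embryo maturation transcription factors, 3 rose and 0 fell (4 and 0 when adjusted over the list alone). They were DPBF2 (AT3G44460, also bZIP67), from 0.426 to 2.02, L1L (AT5G47670), from 1.03 to 2.87, and EEL (AT2G41070), from 100.2 to 172.5. This list had a camera adjusted p of 0.0381, of 0.644 with an estimated correlation, of 0.0835 with the replicate block, of 0.0582 without Col-0 replicate 3 and of 0.0696 with no filter beyond a mean above 0.

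Core histone genes, whose products ASF1 binds in part, were higher as a list. Of 35 measured, 16 rose, 3 fell and 16 did not pass (17 and 3 when adjusted over the list alone; camera adjusted p = 0.0025, adjusted p = 0.83 with an estimated correlation). The H4 gene AT5G59690 rose from 67.8 ± 8.79 to 237 ± 46.1 rescaled TPM (SD, n = 3; limma adjusted p = 0.00127), HTB9 (AT3G45980) from 10.9 to 33.6, HTR2 (AT1G09200) from 2.08 to 12.5 and HTB6 (AT3G53650) from 0.184 to 2.81. HTR2 lost its call without asf1a1b replicate 3 (limma adjusted p = 0.0564, log2 fold change 2.03), and its ratio of means went from 6 to 9.12 without Col-0 replicate 3. Among other histone chaperones 2 of 14 rose and 1 fell (2 and 1 when adjusted over the list alone; camera adjusted p = 0.838), with HIRA (AT3G44530) at 5.93 and 9.13, MSI1 (AT5G58230) at 22.6 and 31.7 and NRP1 (AT1G74560) at 46.5 and 29.5 in Col-0 and asf1a1b. The call of HIRA ended without Col-0 replicate 2, that of MSI1 without Col-0 replicate 1 or 2 or asf1a1b replicate 2 or 3, and that of NRP1 without Col-0 replicate 2 or asf1a1b replicate 3 (limma adjusted p up to 0.053, 0.145 and 0.0693, log2 fold changes there 0.57, 0.41 and -0.54), and MSI1 lost its call under both other scalings.

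Of 21 DNA damage response genes 10 were measured, and of these 2 rose and 2 fell (2 and 2 when adjusted over the list alone; camera adjusted p = 0.534). TSO2 (AT3G27060), a ribonucleotide reductase subunit, rose from 1.34 to 3.21 rescaled TPM, while SYN2 (AT5G40840), a cohesin subunit, fell from 40.8 to 23.1 and AGO2 (AT1G31280) from 7.18 to 4.90. The call of TSO2 ended without asf1a1b replicate 3, that of SYN2 without Col-0 replicate 2 or asf1a1b replicate 2 or 3, and that of AGO2 in all such fits but the one without Col-0 replicate 1 (limma adjusted p up to 0.0509, 0.0981 and 0.153, log2 fold changes there 0.73, -0.72 and -0.34). The call of AGO2 also ended with a mean of at least 5 (limma adjusted p = 0.0589) and with no filter (0.0703). The list members PARP2 (AT4G02390) and GMI1 (AT5G24280), named after their values were seen, are marked up in the authors' deposited table. Their log2 fold changes there are 2.52 and 1.78. The same table marks TSO2, SYN2 and AGO2 as neither up nor down. Of the 4 measured cell cycle and replication genes, 2 rose, ORC6 (AT1G26840) from 0.752 to 2.11 and MCM5 (AT2G07690) from 0.533 to 1.53 (3 and 0 when adjusted over the list alone).

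Photosynthesis genes were higher as a list, and unevenly between mutant libraries. Of 17 measured, 9 rose, 1 fell and 7 did not pass (9 and 1 when adjusted over the list alone; camera adjusted p = 0.00421, adjusted p = 0.83 with an estimated correlation, 0.0707 with genes of a mean of at least 5 and 0.0552 with fry). RBCS1A (AT1G67090), a Rubisco small subunit, rose from 16.8 ± 7.21 to 71.0 ± 21.0 rescaled TPM (SD, n = 3; limma adjusted p = 0.00581), LHCA1 (AT3G54890) from 0.967 to 6.54 and LHCB1.2 (AT1G29910) from 0.126 to 4.28. LHCB1.3 (AT1G29930) had a mean of 11.7 with an SD of 8.72 in the mutant and lost its call without asf1a1b replicate 3 (limma adjusted p = 0.0544, log2 fold change 2.59). The ratio of means of LHCB1.3 was 26.8, and 17.38 without asf1a1b replicate 2, and that of LHCB1.2 was 34, and 69 without Col-0 replicate 3. Transcripts of plastid genes made up 0.0718% ± 0.0356 of the signal in Col-0 and 0.226% ± 0.079 in asf1a1b, and those of mitochondrial genes 0.280% ± 0.0794 and 0.497% ± 0.102 (SD, n = 3; two-sided exact permutation p = 0.1 for each, the smallest that 3 against 3 allows).

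Reactive oxygen genes moved both ways, with 5 of 29 up and 3 down (5 and 3 when adjusted over the list alone; camera adjusted p = 0.564). FSD1 (AT4G25100), an iron superoxide dismutase, rose 3.80 times, the glutathione peroxidase genes GPX2 (AT2G31570) and GPX7 (AT4G31870) were 2.77 times higher and 3.22 times lower, and APX1 (AT1G07890) was 5.09 times higher. The call of GPX2 ended without Col-0 replicate 2 or asf1a1b replicate 2 or 3, that of GPX7 without Col-0 replicate 2 or asf1a1b replicate 3, and that of APX1 in all such fits but the one without asf1a1b replicate 1 (limma adjusted p up to 0.0677, 0.0575 and 0.143, log2 fold changes there 1.06, -1.14 and 1.37). With limma-voom on recovered reads the adjusted p of APX1 was 0.0515. APX1 was 3.33 times higher without asf1a1b replicate 2, and GPX7 5.12 times lower without asf1a1b replicate 1. FLC (AT5G10140), the floral repressor, fell from 27.8 ± 5.45 to 8.10 ± 2.95 (SD, n = 3; limma adjusted p = 0.00416), and the other 5 measured flowering regulators did not pass (0 up and 1 down when adjusted over the list alone; camera adjusted p = 0.534). Of 6 cell wall loosening genes, XTH22 and MAN7 (AT5G66460) rose and XTH5 (AT5G13870) fell (3 and 2 when adjusted over the list alone; camera adjusted p = 0.82). The call of MAN7 ended without Col-0 replicate 2, and that of XTH5 in all such fits but the one without Col-0 replicate 1 (limma adjusted p up to 0.0592 and 0.148, log2 fold changes there 0.97 and -0.45). TT7 (AT5G07990), a flavonoid hydroxylase, rose 2.64 times, 1 of 2 measured flavonoid genes (1 and 0 when adjusted over the list alone). PR4 (AT3G04720) rose 1.67 times, and with SID2 it makes up the 2 measured defence genes (1 and 1 when adjusted over the list alone). The call of PR4 ended without Col-0 replicate 2 or 3 or asf1a1b replicate 3 (limma adjusted p up to 0.0824, log2 fold change 0.60).

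Few markers of seed tissues other than the embryo were measured. Of 15 seed coat markers 2 were measured, and both rose (2 and 0 when adjusted over the list alone): PRX36 and ARA12 (AT5G67360, also SBT1.7), the latter from 118.6 ± 11.2 to 198.6 ± 25.6 rescaled TPM (SD, n = 3; limma adjusted p = 0.00871). Of 9 endosperm markers 1 was measured, EPR1 (AT2G27380), with 9020 ± 1850 in Col-0 and 9936 ± 1040 in asf1a1b (limma adjusted p = 0.706; 0 and 0 when adjusted over the list alone).

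**Figure D4:**
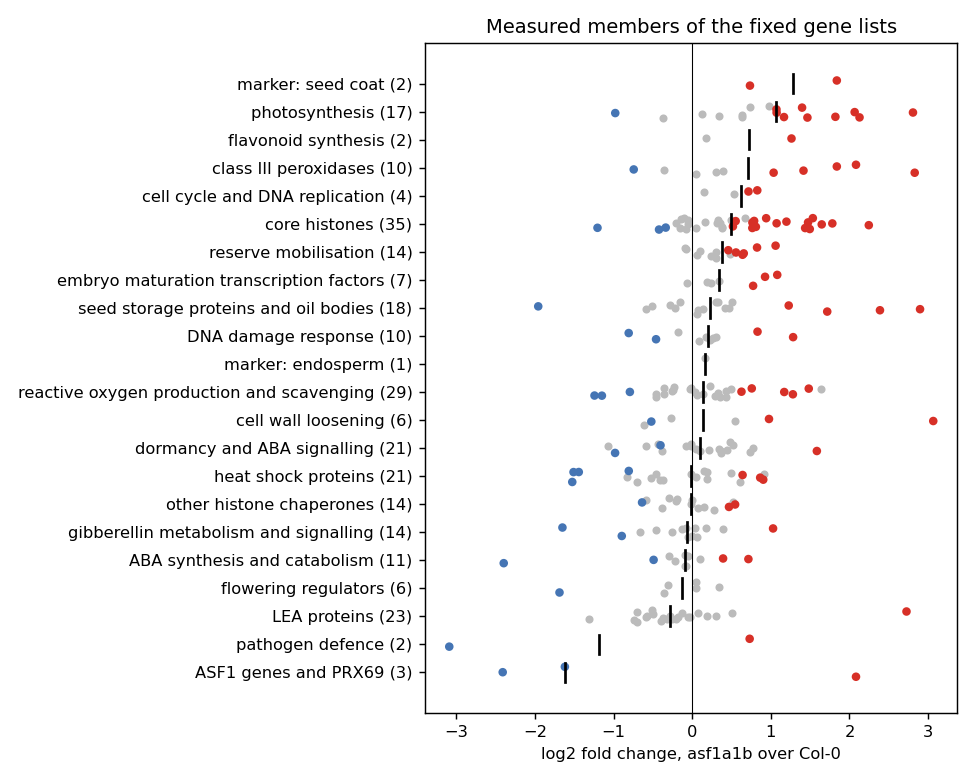
Log2 fold change of asf1a1b over Col-0 (horizontal axis) for each measured member of the fixed gene lists (number of members in brackets), in red or blue where it passed the threshold up or down and in grey where it did not; black ticks are list medians. Core histones, photosynthesis, reserve mobilisation and embryo maturation factors passed the list test with a preset correlation, and 0 lists passed with an estimated one.

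The calls were set beside the authors' deposited table. Among 14188 genes in both, 4370 were called here and 5320 had an adjusted p under 0.05 in the authors' deposited table. Of these, 4332 were called in both with the same direction (2240 up, 2092 down) and 0 with opposite directions, 38 were called here alone and 988 in the authors' deposited table alone. That table marks 951 genes as up and 385 as down, against 3028 higher and 2850 lower genes at its adjusted p under 0.05. Its marks therefore use a stricter rule, which no source names, while the calls here rest on adjusted p alone. Among the named genes, MCM5 with a log2 fold change of 1.508 there is marked up and PRX42 with 1.474 is not. HSFA9 with -1.501 is marked down and HSP21 with -1.456 is not. All 4 have an adjusted p under 0.05 there, and a cut near 1.5 on the size of the change would part them. Of the 951 genes marked up 647 were tested here, and of the 385 marked down 327 were, so a larger share of the up marks went untested. Of the 647 up and 327 down genes tested, 609 and 317 were called in the same direction.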

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

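Limma-voom on recovered reads, the leave-outs of sums, shares and ratios of means, and the thinned peroxidase counts were chosen after seeing the data. The direction of every one of the 4494 called genes that an alternative tested stayed the same in each of the 14 alternatives. The number of genes changed ran from 1767 to 4999 when 1 library was left out, lowest without asf1a1b replicate 3, and was 5825 with the replicate block, which lost 1 list call (embryo maturation factors) and no call of a named gene. It was 2544 with a mean of at least 5, where 9860 genes are tested, and between 4428 and 5055 in the other settings. Genes changed at least 2-fold numbered 886 to 1721 when 1 library was left out, 1382 with the replicate block, 669 with a mean of at least 5, 2002 with a pseudocount of 0.1 and 2045 with limma-voom on recovered reads, since the last pair shrinks low genes less. Gene lists past the threshold numbered 4, and 4 to 6 when 1 library was left out, 3 with the replicate block, 2 with a mean of at least 5 (13 lists tested), 3 with fry, where photosynthesis did not pass (0.0552), and 0 with an estimated inter-gene correlation. The peroxidase list, not called in the main setting, passed without each Col-0 replicate in turn (adjusted p 0.0147 to 0.0259), without asf1a1b replicate 1 (0.0337), with no filter (0.00346) and with the 20 highest genes left out (0.015), and the LEA list passed without asf1a1b replicate 1 (0.0378). With adjusted p under 0.01 in both tables, 1680 genes were shared with the authors' deposited table. ASF1A, ASF1B and PRX69 kept their calls in every setting that tested them. With a mean of at least 5, ASF1B and PRX69 were not tested. The log2 fold change of PRX69 ran from 1.72 to 2.59 when 1 library was left out. It was 4.98 with a pseudocount of 0.1 and 8.28 with limma-voom on recovered reads. That of ASF1B was -3.07 and -3.50 in the same settings, against -1.62 in the main fit. Of the 78 named genes, 48 kept their calls in each fit without 1 library that tested them (MCM5 was tested in 3 of these) and 30 did not. With no filter, where 25774 genes are tested, 13 named genes lost their calls, with adjusted p from 0.0512 (MSI1) to 0.125 (ICL). Median-of-ratios scaling moved the median of all genes from 0.008 to -0.054 and the share of higher calls from 52.6% to 43.7%. The ratio of summed H2A values crossed 1 without Col-0 replicate 2 (0.999), without asf1a1b replicate 3 (0.962) and under that scaling (0.974), and that of H2B (0.942) without asf1a1b replicate 2 (1.01). The cause of these shifts was not tested. Depth limits what can be said of genes at 0 reads, where 3 counts set the floor.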

Other observations

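The tests of histone sums and of green tissue were chosen after the results were seen, and those of depth and of other splits before. A set of genes had recovered reads in the mutant alone. After thinning each library to the same number of reads, 23 genes had at least 5 reads in each asf1a1b library and 0 in every Col-0 library. The other way there was 1 gene. The highest such count on one side of any other split of the libraries was 1. Every other split mixes the genotypes, so a gene that follows genotype cannot be counted there, and that number does not show how unusual 23 is. PRX69 led the 23 by reads, followed by AGL96 (AT5G06500, a MADS-box gene; 59, 113 and 159 reads in asf1a1b replicates 1, 2 and 3), OSM34 (AT4G11650, an osmotin; 5, 48 and 48) and AT5G41740 (a disease resistance gene; 8, 54 and 32). 1 of the 23, BOR4, had 1 read in Col-0 replicate 1 before thinning. The 23 also include the meiotic gene SPO11-2 (AT1G63990) and the cytokinin response regulator gene ARR3 (AT1G59940). All of these but PRX69 were named after their values were seen. SPO11-2 overlaps AT1G63980 and AT1G08647, and without a known strand setting its reads cannot be told from theirs.

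Histone values were also summed by family. Over all 8 H4 genes the sum was 172 ± 14.5 rescaled TPM in Col-0 and 410 ± 73.4 in asf1a1b, over the 3 H3.3 genes 482 ± 66.0 and 792 ± 66.6, and over the 5 H3.1 genes 34.7 ± 4.97 and 47.5 ± 4.54 (SD, n = 3; two-sided exact permutation p = 0.1 each, the smallest possible). The sums over 12 H2A genes (602 ± 45.7 and 616 ± 64.4) and 8 H2B genes (315 ± 23.2 and 296 ± 35.4) gave exact permutation p of 0.6 and 0.5. The difference between the families was not tested.

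One candidate explanation for the rise of H4 genes is that reads were assigned differently among near-identical copies. With copies of like length and every read assigned, that would leave the sum over the 8 genes as it was. The sum was 2.39 times higher, with all 3 mutant libraries above all 3 Col-0 libraries. Splitting of reads under those conditions therefore does not account for the rise, though it can set how the rise is shared among the copies. The sum is of length-scaled values and the read counter is not known. Effects of unlike lengths, or of reads left out because they match several copies, were not tested.

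The genes read in the mutant alone could come from deeper mutant libraries. After thinning, the ratio of mutant-only to Col-0-only genes was still 23, against 25.0 with 25 and 0 genes (0 set to 1) before thinning, so depth does not account for them. Green tissue carried into the mutant libraries stays open. Mutant replicate 2 alone had 404 genes with at least 5 thinned reads and none in Col-0, against 61 and 129 in replicates 1 and 3, and 4 to 11 per Col-0 library against the mutant. Among 127 genes chosen on replicate 3, the median ratio of reads in replicate 1 to replicate 2 was 0.125, against 0.204 for 5 leaf genes (one-sided permutation p = 0.643), which decides nothing. A first version of this test required reads in replicate 1, which itself raises the ratio (0.625, one-sided permutation p = 0.0051), and was replaced after its result was seen. Without asf1a1b replicate 1 the 23 genes became 104, and without Col-0 replicates 1, 2 or 3 they became 57, 42 and 42.

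The photosynthesis genes could also come from green tissue. A list of 20 leaf genes was written for this test, 11 of which had a Col-0 mean of at least 1. Whether that signal came from the seeds themselves or from green tissue in the Col-0 libraries was not tested. Of its 12 measured genes 1 rose and 2 fell, and the abundant leaf gene RCA was at 5.42 and 6.07 in Col-0 and asf1a1b. Each leaf gene below the level tested was low, but higher in every mutant library than in any Col-0 library. All of these were highest in asf1a1b replicate 2, among them CA1 (0.00867 and 0.114), PRK (0.208 and 1.51) and LHB1B1 (0.00767 and 0.125). The excess over Col-0 in asf1a1b replicate 1, as a share of that in replicate 2, had a median of 0.32 over the 9 photosynthesis genes that rose and of 0.158 over 5 leaf genes chosen on replicate 3 (one-sided permutation p = 0.0649). The 9 genes were chosen by a call that used replicates 1 and 2, which can itself raise their share. The permutation also treats genes of the same libraries as independent. A first version with leaf genes chosen on replicate 2, which lowers their share, gave 0.152 (one-sided permutation p = 0.0428) and was replaced after its result was seen. The 5 leaf shares themselves were split, with PSBR (a photosystem II gene and the list's riser, 32.7 and 135) at 1.48 and the other 4 between 0.0884 and 0.204, so the test does not settle whether green tissue or the genotype raised these genes.

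With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 4494 changed genes, 1311 of them at least 2-fold, and the highest of the other splits gave 0 for both. Of the 10 splits, 1 reached each real number. Every other split has both genotypes on each side, which puts the genotype difference into the spread within sides. The 0 calls there therefore cannot be read as evidence against chance. For gene lists the real split gave 4 and the highest other 5, and 5 of the 10 splits gave at least 4. List calls at the preset correlation thus also arose in splits that mix the genotypes. The number of lists called does not set the real split apart. The 3 other splits that part all 3 same-numbered pairs gave 1 to 3 lists and 0 genes.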
